A study of Mus musculus with 42 samples.

How the data were processed

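Mouse D3 embryonic stem cells were differentiated towards osteoblasts, and total RNA was taken on days 4 to 6 and on day 8, day 16, day 25 and day 30, per the labels. There were 3 replicates on each of the 7 days, so 21 RNA samples. Each RNA was hybridised to 2 Affymetrix mouse chips, MOE430A (430A below) and MOE430B (430B), which gives 42 arrays. The growth protocol in the labels names vitamin D3, beta-glycerophosphate and ascorbic acid for all samples, while the titles name VD3 from day 6 on, so day and that label change together. No untreated or undirected cultures are among the samples analysed here. The labels do not say whether the replicates of a day are separate cultures, so the p-values measure the spread between these samples.

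The deposited values are MAS5 signal, per the submitters' processing notes, with no version and no detection calls in the sources used here. The deposited signal had been scaled by the authors so that the mean of each array without its highest and lowest 2% of values was 1501 on 430A and 1500 on 430B, which was checked on every array. The values had no log and no further step between arrays. Their lowest and highest were 0.3555 and 289067 on 430A and 1.106 and 1090820 on 430B. The chips hold 22690 and 22575 probe sets, of which 64 on each are controls. Arrays carry no read depth, and the number of arrays limits the precision.

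Gene symbols came from the platform annotation and were matched by Entrez identifier to a table of mouse genes for assembly GRCm38.p6, which found 20364 probe sets on 430A and 14499 on 430B and changed 0 symbols. On 430A 20393 probe sets had 1 symbol, 691 had several and 1606 had none, and on 430B these numbers were 14674, 245 and 7656. No coordinates were used. Over 100 probe sets present on both chips, 18 of the 21 RNA samples correlated best with the array of their own RNA on the other chip (median r 0.685 for the same RNA and -0.0745 for other RNAs).

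Signals were taken to log2 with no offset. A probe set was tested where it lay above its array's 40th percentile on at least 3 of the 21 arrays, which kept 16705 probe sets (73.8%) on 430A and 18260 (81.1%) on 430B, together 34965. Each chip was fitted by itself in limma 3.58.1 (R 4.3.3, data.table, version 1.17.8) with day as a factor over all 21 arrays, which leaves 14 residual degrees of freedom, followed by eBayes with a trend. Where a value of the day with the lower mean lay under the chip's 20th percentile over all arrays (log2 6.96 on 430A and 7.67 on 430B), the fold or difference is a lower bound, written as "at least". For this bound each such value was raised to that percentile and the other day's mean was used as it stood, a rule chosen after the data were examined. Folds without single arrays are differences of day means, taken the same way, and no adjusted p comes from them. Adjusted p-values are limma's, two-sided, with the Benjamini-Hochberg method over the probe sets of each chip and comparison, and a threshold of 0.05. Counts are sums over both chips. The comparisons were the F test over the 7 days, day 30 with day 4, the 6 successive steps, and each later day with day 4 for the osteoblast markers. Day 16 with day 6 was added after the data were examined, because both days lie in 1 scan batch on both chips.

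There were 24 gene lists, written from general knowledge of the cell types and pathways. They cover the RT-PCR markers that the labels name, osteoblast, vitamin D response, pluripotency, primitive streak and early mesoderm, endoderm, cartilage, extracellular matrix, cardiac, smooth and skeletal muscle, neural, endothelial, erythroid, macrophage and osteoclast, adipocyte, simple and stratified epithelium, trophoblast, cell division, Hox, BMP and Wnt signalling, interferon response, and stress and hypoxia genes. A gene stands for its 430A probe set with the highest mean, or its 430B probe set where 430A has none that was tested. Lists were tested with camera (limma) with a preset correlation of 0.01 on the 430A genes, two-sided, with Benjamini-Hochberg adjustment over the 24 lists of each comparison, and again with a correlation estimated for each list. That second run also tests on the residual degrees of freedom of the fit, so its p differs even for the RT-PCR list, which has 1 gene and no correlation. Below, the p for a list is camera's adjusted p. "Adjusted over the list alone" means that the Benjamini-Hochberg step used the members of that list only.

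Genes are named by a rule. For day 30 with day 4 these are the 10 largest rises and 10 largest falls among genes past the threshold whose 3 values on a day all lie above the 3 on the other and whose mean is above the median of the tested probe sets. For each successive step they are the 5 largest in each direction by the same rule. Also named are the RT-PCR markers and, for each list described, up to 4 members with the largest change past the threshold, or the 2 with the smallest adjusted p where none passed. Chance alone makes the values of 3 against 3 arrays separate in 10% of genes. In each comparison, the other probe sets of the genes so named either changed the same way or did not pass.

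The settings files of the arrays carry scan information, which sorts the arrays into scan batches. On 430A, days 4 and 5 form a batch of 6 arrays, days 6, 8 and 16 a batch of 9, day 25 replicates 1 and 2 with day 30 a batch of 5, and day 25 replicate 3 a batch by itself. On 430B the batches are the same up to day 16 except that day 5 replicate 1 was scanned with days 6, 8 and 16, and days 25 and 30 are spread over 3 batches. Day 30 with day 4, day 25 with day 16 on both chips and day 6 with day 5 on 430A lie wholly between batches, as do days 6, 8, 16 and 25 with day 4 on 430A, so day and scan batch cannot be told apart there. The other steps lie within a batch or are linked by shared batches.

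The same files write culture numbers 1, 2 and 3 for the RNAs, except that replicate 3 of days 8 and 16 is written as culture 4. Whether replicate numbers pair the samples of different days was checked with the correlation, across probe sets, of each sample's deviation from its day. On 430A all 3 pairs lay above 0.1 for days 4 and 5 (r 0.161 to 0.21) and for days 6 and 8 (0.108 to 0.118), while days 5 and 6 gave 0.07 to 0.355 and days 4 and 30 gave -0.003 to 0.012. On 430B no comparison had all 3 above 0.1. The tests use no block, and for day 5 with day 4 and day 8 with day 6 the count with the replicate number as a block is given beside the count without it.

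The alternatives were quantile normalisation, median centring, an offset of the 20th percentile before log2, no filter, a filter at the 60th percentile, eBayes without the trend, only the arrays of the days compared, the replicate number as a block, scan batch as a block, a required change of 2-fold, and leaving out each replicate in turn. For named genes, they were quantile normalisation, the offset and the replicate block. For lists, they were quantile normalisation, the estimated correlation, the mean over a gene's probe sets and leaving out each replicate in turn. These alternatives, the comparisons except day 16 with day 6, the lists and the rule for names were chosen before the data were examined. Added after the data were examined were the culture number as a block, the Gapdh 3'/5' ratio as a covariate, scan batch as a random block, leaving out each replicate for the named genes, every alternative for the osteoblast marker courses, the replicate block on the compared days alone, and a fit without the arrays of day 4 replicate 2 and day 25 replicate 1. The tests were run on simulated data first. Known changes between day 25 and day 30 were put into simulated data. limma called 14.2% of 2-fold ones (19 of 134), 53.0% of 4-fold (71 of 134) and 72.7% of 8-fold (96 of 132). It also called 13 unchanged ones.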

Results

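Gene expression was followed in mouse D3 embryonic stem cells, a line from the inner cell mass of the blastocyst, while the cultures were directed towards osteoblasts, the cells that lay down bone matrix. The course had 7 days with 3 RNA samples each, and every RNA was measured on 2 chip types, 430A and 430B. Of the probe sets, 34965 were tested. The deposited signal had been scaled to a common trimmed mean on each chip, and the array medians were 473.9 to 681.9 on 430A (highest on day 25 replicate 1) and 790.4 to 900.8 on 430B. The median correlation with the other replicates of the same day was 0.869 on day 4, 0.923 on day 16 and 0.91 on day 30 on 430A, and 0.737, 0.794 and 0.744 on 430B. The log2 ratio of signal from the 3' and 5' ends of the Gapdh control transcript, which rises as RNA shortens, was 2.63 ± 0.37 on day 4 (SD, n = 3), 2.55 ± 0.15 on day 16, 3.84 ± 0.38 on day 25 and 3.27 ± 0.19 on day 30 on 430A, while the same ratio for actin was 2.62, 2.19, 2.63 and 2.49 on these days. Statements below about levels are log2 signal, and changes with their standard errors (SE) are on the log2 scale with 3 arrays per day.

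Among genes that differed between days, the bone matrix protein gene Sparc rose from 12.33 ± 0.78 on day 4 (SD, n = 3) to 17.03 ± 0.23 on day 30, and the vitamin D hydroxylase gene Cyp24a1 from 6.60 ± 1.68 to 12.99 ± 0.35. Fgf5, a gene of the epiblast, fell from 13.40 ± 0.64 to 7.42 ± 0.33. The F test over all 7 days asked which probe sets differ between any days. It called 7822 probe sets (22.4% of those tested), of which 6048 were on 430A (36.2%) and 1774 on 430B (9.71%). In a principal component analysis of 430A, PC1 took 35.0% of the variance and PC2 14.2%, and on 430B they took 14.3% and 9.0%. On PC1 of 430A the day 4 arrays lay at -67.4, -71.6 and -75.0 and the day 30 arrays at 77.8, 65.5 and 70.6. Day 6 replicate 3 lay at -60.1, nearer to day 4 than the other arrays of day 6 at -34.8 and -42.0.

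**Figure D1:**
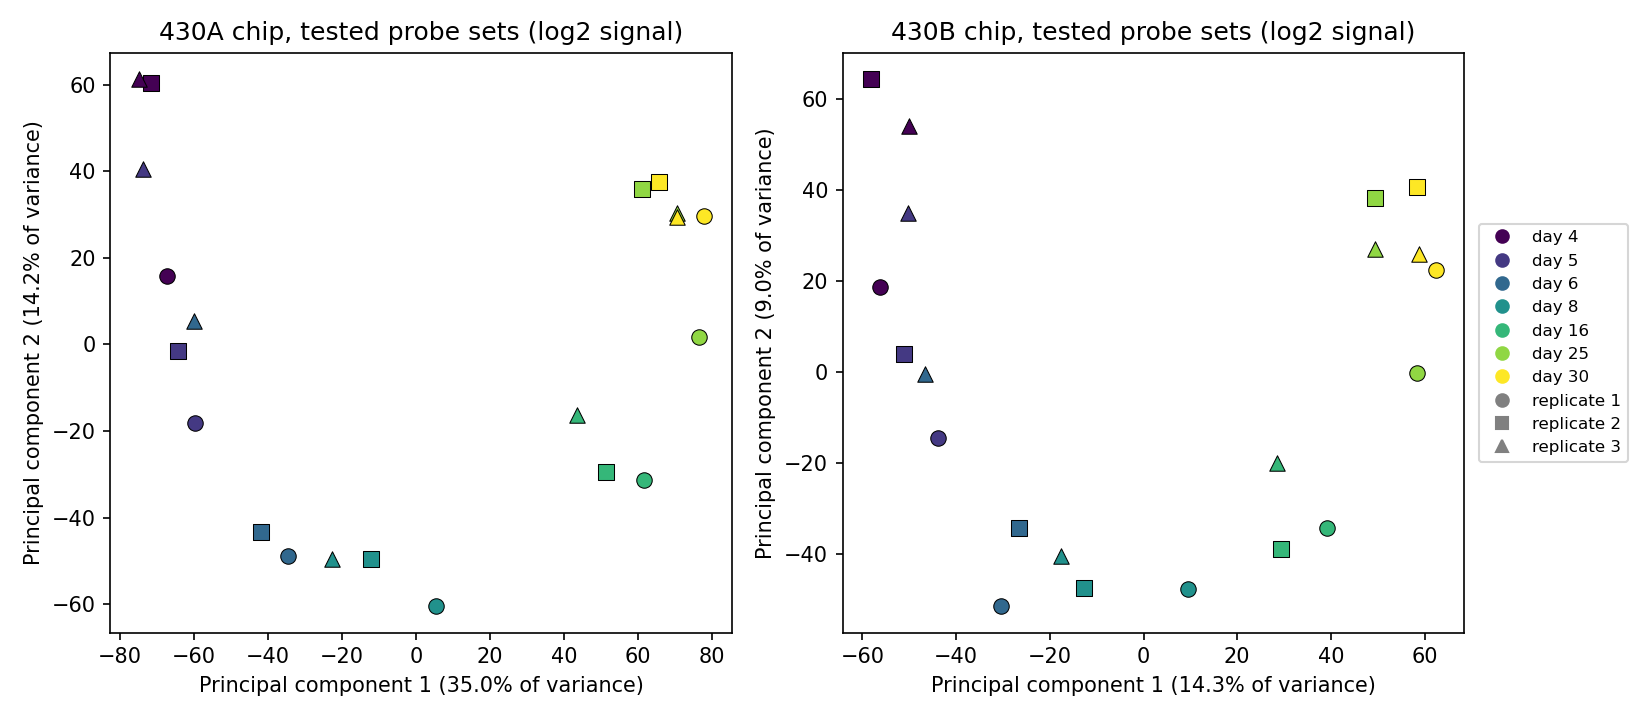
Principal components of log2 signal for the 430A chip (left) and the 430B chip (right), with 1 point per array coloured by day and the share of variance on each axis. The days follow each other along an arc from day 4 to day 30, with PC1 at 35.0% of the variance on 430A and 14.3% on 430B.

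**Figure D2:**
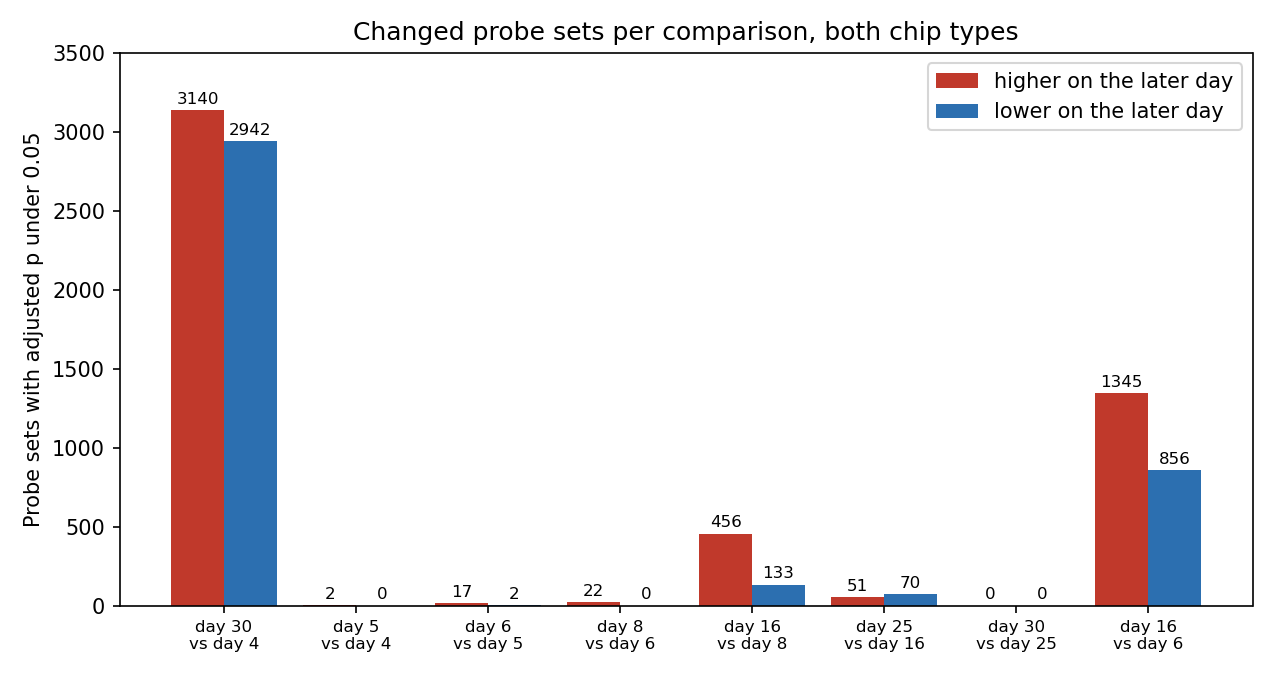
Number of probe sets past an adjusted p of 0.05 in each comparison, drawn as higher (up) and lower (down) on the later day, summed over both chips. Day 30 with day 4 has 3140 higher and 2942 lower, and among successive steps day 16 with day 8 has the most with 456 higher and 133 lower.

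Between day 4 and day 30, Sparc, whose protein binds collagen and mineral in bone, rose 25.9-fold (4.70, SE 0.41, adjusted p = 8.0e-08). Cyp24a1, which vitamin D induces to break down its own hormone, rose at least 49.8-fold (adjusted p = 6.2e-08). Here and below, "at least" marks a lower bound for genes with a value under the chip's 20th percentile on the day with the lower mean. Tdgf1, a Nodal co-receptor of pluripotent cells, was at least 67.5-fold lower (adjusted p = 3.8e-05), and Pou5f1, which maintains pluripotency, was at least 29.7-fold lower (adjusted p = 4.7e-04). Lama1, a laminin chain of early basement membranes and of parietal endoderm, rose from 8.80 ± 0.24 to 15.12 ± 0.14 (SD, n = 3; 79.7-fold, SE 0.73, adjusted p = 2.8e-06).

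Further rises were those of the membrane protein gene Emp1 (at least 49.2-fold), the gastric gene Gkn2 (at least 93.9-fold), the fetal plasma protein gene Afp (at least 53.2-fold), the proteoglycan Dcn (52-fold, SE 0.70), the chaperone genes Cryab (at least 35.9-fold) and Clu (49.8-fold, SE 0.37), the matrix gene Tinagl1 (46.5-fold) and the pantetheinase gene Vnn1 (38.7-fold). Emp1 went from 5.92 ± 2.61 on day 4 to 12.89 ± 0.80 on day 30. The falls included those of Fgf5 (at least 51.6-fold, adjusted p = 1.9e-04) and the phosphatase gene Mtm1 (-5.97, SE 0.47, 62.8-fold lower, adjusted p = 2.7e-08). Others were those of the imprinted gene Phlda2 (at least 38.3-fold), the germ and stem cell gene Dppa5a (-5.07), the signalling gene Nodal (-4.68, SE 0.47, adjusted p = 4.8e-07), Tcfl5 (-4.61), Snhg14 (-4.59), Vrtn (at least 17.7-fold), Mdn1 (at least 16.4-fold) and the splicing regulator Ptbp1 (at least 12-fold). For Emp1, Cyp24a1 and Dcn 1 other probe set each did not pass, and for Mdn1 and Ptbp1 2 each. Without day 4 replicate 1 the fold for Afp was at least 121 and Dppa5a was at -6.10. Without day 4 replicate 2 the fold was at least 148 for Gkn2, 54.6 for Cryab and 23.9 for Phlda2. Without day 4 replicate 3 it was at least 29 for Afp and 75.3 for Phlda2, and Dppa5a was at -4.41. For Vrtn it was at least 26.8 without day 30 replicate 2.

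Of the RT-PCR markers that the labels name, 1 was measured, Sparc, and it rose (camera adjusted p = 0.0139, but 0.0977 in the run with estimated correlations, which a list of 1 gene does not have). The list held 5 markers, 2 named on the chips and 1 with a tested probe set. The other named marker did not pass the filter on low signal, and the rest were not analysed here. Of 32 osteoblast genes listed, 26 were named on the chips and 16 were measured, that is, passed that filter. The counts and list test leave out the rest. Of these 16, 7 rose, 1 fell and 8 did not pass, with 7 and 2 when adjusted over the list alone. Examples are the parathyroid hormone receptor gene Pth1r (at least 12.8-fold, adjusted p = 0.0087, but 6.58-fold and 0.0692 without day 4 replicate 3), Bmp2 (at least 6.95-fold, adjusted p = 0.00566, but 4.47-fold without day 4 replicate 3) and the collagen gene Col1a2 (16.8-fold, SE 0.66, adjusted p = 1.1e-04, and 26.8-fold without day 4 replicate 1). The osteoblast list passed with a median of 0.35 (adjusted p = 0.0437, but 0.449 with an estimated correlation), and its call was lost without day 4 replicate 3 (adjusted p = 0.232) or day 30 replicate 1 (adjusted p = 0.0675). Of 9 vitamin D response genes 4 rose, 0 fell and 5 did not pass, the same 4 and 0 adjusted over the list alone, with a median of 1.11 (adjusted p = 0.00498, but 0.0977 with an estimated correlation). Next to Cyp24a1 these were the calcium-binding protein gene S100g (at least 6.02-fold), the cell cycle inhibitor gene Cdkn1a (7.09-fold, SE 0.23, adjusted p = 3.4e-08) and the calcium channel gene Trpv6 (4.96-fold, SE 0.52).

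Pluripotency genes fell as a group, with 28 measured, 1 risen, 15 fallen and 12 not past the threshold (1 and 16 adjusted over the list alone, median -1.96, adjusted p = 1.2e-05, but 0.277 with an estimated correlation). Nanog, a core factor of the pluripotent state, was at least 10-fold lower (adjusted p = 0.0046). Of 23 genes of the primitive streak and early mesoderm, 2 rose, 11 fell and 10 did not pass (2 and 14 adjusted over the list alone, median -1.73, adjusted p = 0.00226, but 0.284 with an estimated correlation). Mixl1, which marks the streak, was at least 15.6-fold lower (adjusted p = 0.00154, 23.5-fold without day 4 replicate 3). Lhx1 was at least 12.3-fold lower (adjusted p = 0.00757, but 0.0571 and 5.53-fold without day 4 replicate 2, and 31.6-fold without day 4 replicate 3). The mesoderm receptor gene Pdgfra went the other way and rose at least 12-fold (adjusted p = 0.00158, 26.3-fold without day 4 replicate 1 and 5.77-fold without day 4 replicate 3). Cell division genes also fell, with 19 of 37 lower, 0 higher and 18 not past the threshold (23 lower and 0 higher adjusted over the list alone, median -0.79, adjusted p = 4.5e-09, but 0.199 with an estimated correlation). Cdc20, which drives exit from mitosis, was 5.82-fold lower (-2.54, SE 0.30, adjusted p = 3.7e-06), and the replication helicase gene Mcm7 was 4.18-fold lower (-2.06, SE 0.24).

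Endoderm genes, which make plasma proteins and yolk sac products, had a median of 2.23, with 17 of 27 risen, 0 fallen and 10 not past the threshold (19 and 0 adjusted over the list alone, adjusted p = 3.3e-07, but 0.264 with an estimated correlation). Besides Lama1 and Afp, the fibrinogen genes Fgb and Fga rose at least 10.5-fold (adjusted p = 7.0e-04) and 5.49-fold (adjusted p = 0.00192). Of 48 extracellular matrix genes 27 rose, 1 fell and 20 did not pass (29 and 2 adjusted over the list alone, median 2.13, adjusted p = 5.0e-13, but 0.0977 with an estimated correlation). The basement membrane gene Nid1 rose 35.9-fold (5.17, SE 0.40, adjusted p = 2.7e-08) and the collagen gene Col4a2 30.7-fold. Of 17 simple epithelium genes 8 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone, median 0.96, adjusted p = 0.00127, but 0.197 with an estimated correlation). They included Lcn2 (at least 78.1-fold) and Krt7 (16.5-fold, SE 0.31, adjusted p = 2.2e-08). Stratified epithelium genes gave 6 of 14 risen, 0 fallen and 8 not past the threshold (6 and 0 adjusted over the list alone, median 1.41, adjusted p = 0.00183, but 0.197 with an estimated correlation). These included the basal keratin genes Krt14 (at least 26.9-fold) and Krt15 (at least 9.01-fold, and 5.83-fold without day 30 replicate 1). Of 23 macrophage and osteoclast genes 7 rose, 0 fell and 16 did not pass (8 and 0 adjusted over the list alone, median 1.11, adjusted p = 0.00254, but 0.449 with an estimated correlation). Among them were the growth factor receptor gene Csf1r (8.22-fold, SE 0.39, adjusted p = 8.1e-06) and Itgb3 (at least 5.04-fold), an integrin of osteoclasts.

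Stress and hypoxia genes were the only list that passed with the estimated correlation as well (adjusted p = 9.1e-07, and 0.0449 with an estimated correlation). Of its 26 genes 16 rose, 3 fell and 7 did not pass (18 and 3 adjusted over the list alone, median 1.26). Fos and Atf3 both rose 18.4-fold, Egr1 13-fold (8.19-fold and 20.7-fold without day 4 replicates 2 and 3) and the hypoxia target Vegfa at least 9.79-fold (17-fold and 6.01-fold without day 4 replicates 1 and 2). Interferon response genes passed with 5 of 17 risen, 1 fallen and 11 not past the threshold (8 and 1 adjusted over the list alone, median 1.00, adjusted p = 0.0214, but 0.393 with an estimated correlation). In this list B2m, a chain of MHC class I, rose 5.2-fold (2.38, adjusted p = 4.1e-08), while the proteasome gene Psmb9 was at least 4.79-fold lower (adjusted p = 0.00318). Neural genes passed downwards, with 1 of 22 risen, 5 fallen and 16 not past the threshold (1 and 5 adjusted over the list alone, median -0.70, adjusted p = 0.0313, but 0.277 with an estimated correlation and 0.0701 without day 4 replicate 3). Crmp1, a growth cone gene, was at least 9.88-fold lower (adjusted p = 2.7e-04).

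The remaining lists did not pass. Of 22 cardiac genes 4 rose, 0 fell and 18 did not pass (2 and 0 adjusted over the list alone, median 0.38, adjusted p = 0.363). The myosin light chain gene Myl3 was 8.23-fold higher (adjusted p = 0.0079). Smooth muscle genes gave 3 of 13 risen, 1 fallen and 9 not past the threshold (3 and 1 adjusted over the list alone, median 0.54, adjusted p = 0.363). Mylk was at least 6.21-fold higher (adjusted p = 6.1e-04) and the calponin gene Cnn1 lower (-2.23, adjusted p = 0.0147, but 0.0716 without day 4 replicate 2). Of 15 skeletal muscle genes none passed in either count (median 0.90, adjusted p = 0.387), Mylpf (adjusted p = 0.221) and Acta1 (0.157) among them. None of 17 cartilage genes passed in either count (median -0.10, adjusted p = 0.757). Cilp had an adjusted p of 0.278 and Col11a2 of 0.328. None of 13 erythroid genes passed in either count (median -1.17, adjusted p = 0.437). Slc4a1 had an adjusted p of 0.082 and Tal1 of 0.0586. Of 16 endothelial genes 5 rose, 1 fell and 10 did not pass (5 and 1 adjusted over the list alone, median 0.55, adjusted p = 0.437). Esam was 3.86-fold higher (adjusted p = 0.00256). Adipocyte genes gave 2 of 7 risen, 0 fallen and 5 not past the threshold (2 and 0 adjusted over the list alone, median 0.37, adjusted p = 0.363). The lipase gene Lpl was 4.09-fold higher (adjusted p = 0.00308). Trophoblast genes gave 1 of 9 risen, 2 fallen and 6 not past the threshold (1 and 4 adjusted over the list alone, median -1.27, adjusted p = 0.363). Eomes was 10.5-fold lower (-3.40, adjusted p = 5.0e-04). Of 23 Hox genes 1 rose, 1 fell and 21 did not pass, the same adjusted over the list alone (median 0.25, mean -0.03, a downward direction in the test, adjusted p = 0.757). Hoxd1 was at least 3.77-fold lower (adjusted p = 8.7e-04). Of 40 BMP and Wnt signalling genes 10 rose, 8 fell and 22 did not pass (11 and 10 adjusted over the list alone, median 0.14, mean -0.06, an upward direction in the test, adjusted p = 0.826). Lef1 was at least 3.19-fold lower (adjusted p = 0.00603) and Dkk2 at least 3.54-fold higher (adjusted p = 0.0081, but 0.0522 without day 4 replicate 2).

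In all, 6082 probe sets changed between day 4 and day 30 (17.4% of those tested), 3140 upwards and 2942 downwards, and 4735 of them at least 2-fold. The comparison lies wholly between scan batches, so day and batch cannot be told apart. Every Gapdh 3'/5' ratio was higher on day 30 than on day 4. Used as a covariate (4861 passed), it cannot tell RNA shortening from day. Median centring shifted the 430B median change by 0.104.

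The osteoblast markers were followed against day 4 because the labels report RT-PCR results for such markers in these cultures. The fibrillar collagen gene Col1a1, the main protein of bone matrix, rose 7.3-fold by day 6 (2.87, SE 0.69, adjusted p = 0.0177, but 0.0694 to 0.0888 without day 4 replicate 2, day 4 replicate 3, day 6 replicate 1 or day 6 replicate 2), was 32.6-fold higher on day 16 (5.03), and 16.7-fold on day 30 (4.07, adjusted p = 1.8e-04). Without day 4 replicate 1 these were 3.83, 5.98 and 5.02, and without day 4 replicate 3 they were 2.26, 4.42 and 3.46. Its partner Col1a2 was highest on day 16, at 56.7-fold (5.82, SE 0.66, adjusted p = 4.0e-06, and 6.50 without day 4 replicate 1). Sparc had its highest day mean on day 30. It was not called on day 5 (0.42, adjusted p = 0.805) or day 6 (1.13, adjusted p = 0.09), and it rose by 2.33 on day 8 (adjusted p = 7.9e-04), 3.11 on day 16, 4.08 on day 25 and 4.70 on day 30. Alpl, the alkaline phosphatase gene whose enzyme frees phosphate for mineral, did not rise and was at least 3.82-fold lower on day 8 (adjusted p = 0.0178, but 0.0978 and 0.135 without day 4 replicate 2 and day 8 replicate 1, and 5.73-fold without day 8 replicate 2). The osteoblast transcription factor gene Sp7 was not called on day 30 (0.37, adjusted p = 0.502).

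**Figure D3:**
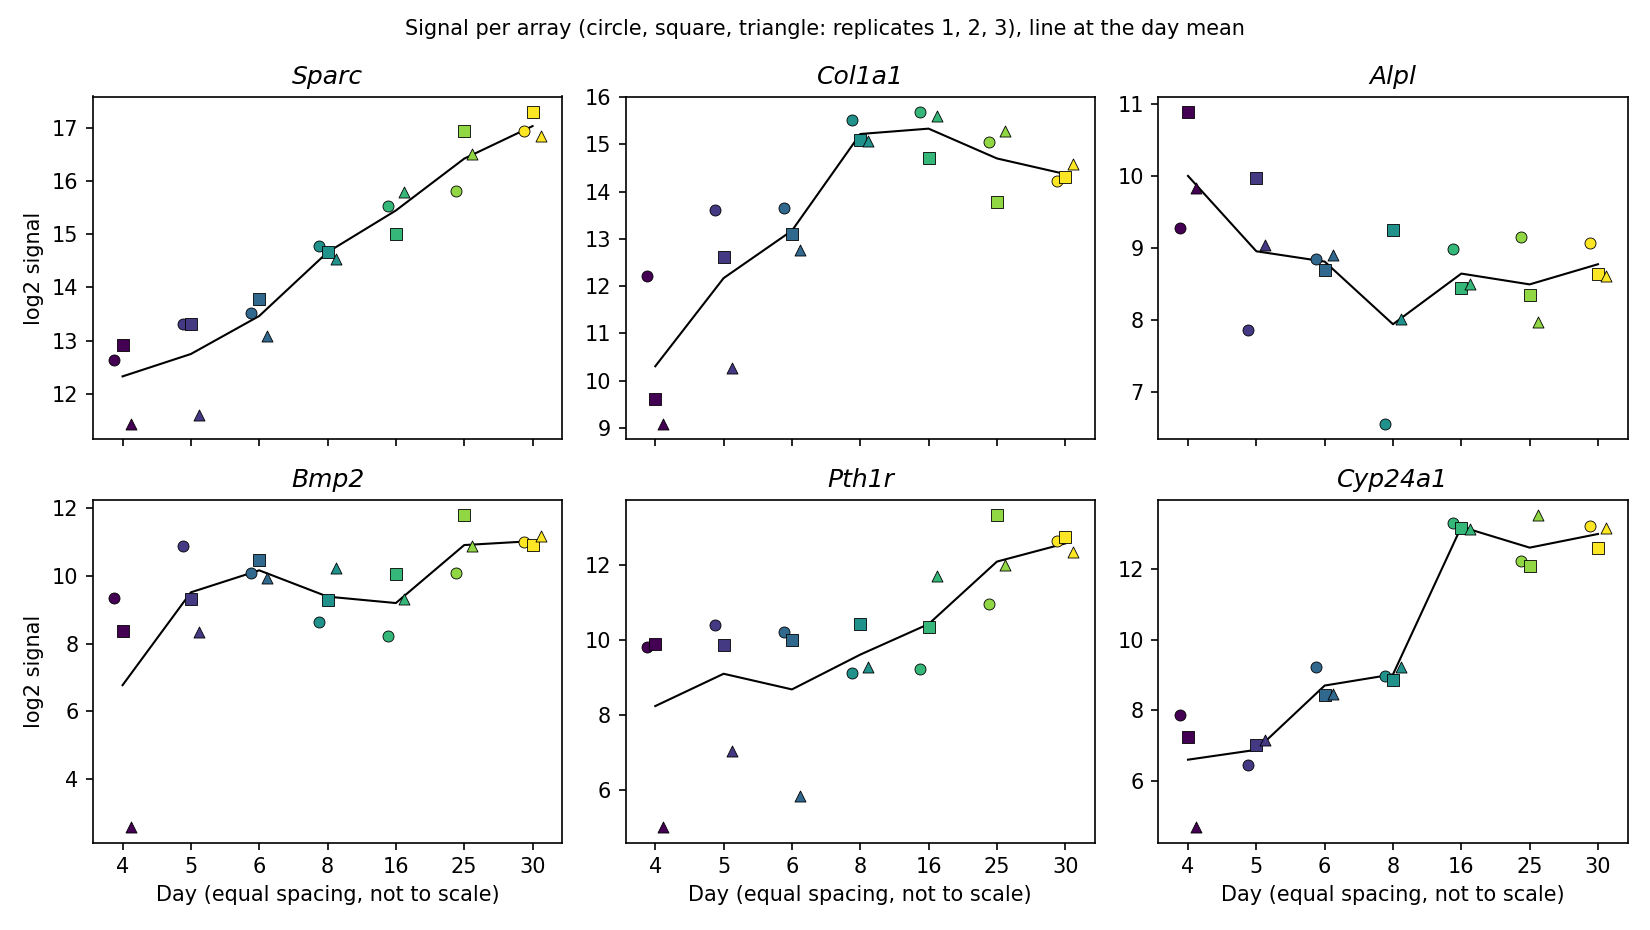
Log2 signal of Sparc, Col1a1, Alpl, Bmp2, Pth1r and Cyp24a1 on the 430A chip by day, with 1 point per array and a line through the day means. Sparc ends at 17.03 on day 30, and Cyp24a1 goes from 9.01 on day 8 to 13.19 on day 16.

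Of the 16 measured osteoblast genes, 0 passed on day 5, 1 rose on day 6, 6 rose and 1 fell on days 8 and 16, 7 rose and 0 fell on day 25, and 7 rose and 1 fell on day 30. Adjusted over the list alone, these were 0 on day 5, 5 on day 6, 6 and 1 on days 8 and 16, and 7 and 2 on days 25 and 30. The 6 genes that rose on days 8 and 16 were Ank, Cdh11, Col1a1, Col1a2, Serpinf1 and Sparc. Ank on day 8 was not called without day 8 replicate 1 (adjusted p = 0.0863) or 2 (0.0647). By days 25 and 30 the cadherin gene Cdh11 was not called (-0.12, adjusted p = 0.912, and -0.64, 0.475). Both depend on day 4 replicate 3, at 7.32 against 10.4 and 10.12. Bmp2 had joined, at least 6.43-fold higher on day 25 (adjusted p = 0.00769, but 4.13-fold without day 4 replicate 3). So did Pth1r, at least 9.18-fold (0.0197). Without day 4 replicate 3 Pth1r was 4.7-fold higher and not called (0.146), and without day 25 replicate 2 at least 5.99-fold and not called (0.0851). Serpinf1, which makes a secreted factor of bone, peaked on day 16 (3.10, 8.58-fold, adjusted p = 1.1e-05). Msx2 was lower on day 16 (-1.97, adjusted p = 0.0492, but -1.34 and 0.218 without day 4 replicate 1, -1.20 and 0.269 without day 4 replicate 2, 0.127 and 0.144 without day 16 replicates 1 and 2, and -3.39 without day 4 replicate 3). Bmp4 was lower on day 30 (-2.67, 6.37-fold, adjusted p = 0.00263, and -3.39 without day 4 replicate 3). Together there were 27 rises and 3 falls over the 6 later days, and all of them share the day 4 arrays. On 430A, where they were all measured, each day from day 6 on lies in another scan batch than day 4, so day and batch cannot be told apart.

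From day 4 to day 5 the integrin gene Itgb3, later a surface marker of osteoclasts, rose at least 7.01-fold, from 7.18 ± 0.37 to 10.48 ± 0.84 (SD, n = 3; adjusted p = 3.0e-04). Embryonic globin genes were higher on average, but no call was made: the difference was 4.00 for Hba-x (SE 1.25, adjusted p = 0.491) and 3.89 for Hbb-bh1 (SE 1.24, adjusted p = 0.491). The list of 13 erythroid genes passed upwards (0 past the threshold, 2 and 0 adjusted over the list alone, median 1.10, adjusted p = 1.2e-04, but 0.57 with an estimated correlation and 0.123 without day 5 replicate 1). The 28 pluripotency genes passed downwards (0 past the threshold, 0 risen and 3 fallen adjusted over the list alone, median -1, adjusted p = 3.1e-07, but 0.57 with an estimated correlation and 0.0511 without day 4 replicate 3). Among them the difference was -1.92 for Nodal (adjusted p = 0.358) and -1.73 for Fgf4 (adjusted p = 0.374).

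This step, within 1 scan batch except for day 5 replicate 1 on 430B, asked what changed in the last days before the titles name VD3. Within that batch on 430A, the log2 signal of the BioB control still differed, at 12.11 to 12.52 on day 4 and 11.45 to 11.70 on day 5. What this means for the step was not tested. limma called 2 probe sets, both higher, while 2598 had an unadjusted p under 0.05. With the replicate number as a block it called 7, of which 5 were higher and 2 lower. The count was 209 without day 4 replicate 1, 78 without day 5 replicate 3, 5 without day 4 replicate 3 and 1 without day 5 replicate 1.

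Between day 5 and day 6, when the titles begin to name VD3, Tagln, an actin-binding gene of smooth muscle, rose 9.2-fold (3.20, SE 0.46, adjusted p = 0.00795). Ccn1, a matrix protein gene induced by serum and stretch, rose 6.06-fold (2.60, SE 0.31, adjusted p = 7.5e-04) from 10.31 ± 0.36 to 12.91 ± 0.60 (SD, n = 3), and 1 of its 3 other probe sets rose as well. Ankrd1 rose at least 6.4-fold (adjusted p = 0.0163), Fos 6.46-fold (2.69, SE 0.40, adjusted p = 0.009, and 10.1-fold without day 6 replicate 3), Egr1 6.75-fold (2.76, SE 0.50, adjusted p = 0.0354, but 0.0516 after quantile normalisation) and Atf3 by 2.06 (SE 0.40, adjusted p = 0.046, but 0.0891 after quantile normalisation and 0.111 with the offset). Atrx was 3.13-fold lower (-1.64, SE 0.31, adjusted p = 0.0446), which none of its 5 other probe sets showed. The vitamin D target Cyp24a1 was not called at this step (at least 1.66, adjusted p = 0.274). Of 9 vitamin D response genes 0 passed (camera adjusted p = 0.473), with 1 risen when adjusted over the list alone, Cyp24a1 itself. Its values were 6.46, 7.02 and 7.15 on day 5 and 9.21, 8.42 and 8.46 on day 6.

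Smooth muscle genes passed upwards (13 measured, 1 risen, 6 and 0 adjusted over the list alone, median 0.92, adjusted p = 7.2e-08, but 0.105 with an estimated correlation). So did cardiac muscle (22 measured, 0 risen, 9 and 1 adjusted over the list alone, median 1.39, adjusted p = 1.9e-06, but 0.484 with an estimated correlation). The difference was 3.37 for the cardiac actin gene Actc1 (adjusted p = 0.266, but 0.0463 with the replicate number as a block) and 2.33 for the atrial myosin gene Myl7 (adjusted p = 0.284). Endothelial genes passed too (16 measured, 0 risen, 2 and 0 adjusted over the list alone, median 0.65, adjusted p = 6.7e-06, but 0.381 with an estimated correlation). The difference was 1.74 for Tek (adjusted p = 0.216) and 1.10 for Cdh5 (adjusted p = 0.146). Extracellular matrix genes passed with Ccn1 the 1 of 48 called (3 and 0 adjusted over the list alone, median 0.38, adjusted p = 4.0e-04, but 0.802 with an estimated correlation and 0.237 without day 5 replicate 3). Stress and hypoxia genes did not (26 measured, 3 risen, 0 fallen, 4 and 3 adjusted over the list alone, adjusted p = 0.531). They had a median of -0.16 and a mean of 0.14 against a downward direction in the test.

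In this step 19 probe sets passed, 17 higher and 2 lower, 17 of them on 430A, where day and scan batch cannot be told apart, and 2431 had an unadjusted p under 0.05. Median centring shifted the 430A median change by -0.121 and gave 10 higher and 5 lower. The count was 91 without day 6 replicate 3, 2 without day 6 replicate 1 or 2, 7 without day 5 replicate 2 and 10 without day 5 replicate 3. Without day 6 replicate 2, Tagln (adjusted p = 0.0596), Ankrd1 (0.144), Fos (0.0647), Egr1 (0.251), Atf3 (0.337) and Atrx (0.318) were not called, nor were they without day 6 replicate 1 (0.0809, 0.165, 0.111, 0.247, 0.252 and 0.174). Without each array of day 5 in turn, Egr1 (adjusted p 0.0571 to 0.13), Atf3 (0.0882 to 0.13) and Atrx (0.0846 to 0.13) were not called, nor was Ankrd1 without day 5 replicate 3 (0.0795). Ccn1 was called with any 1 of the 6 arrays left out.

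From day 6 to day 8 the fibrillar collagen gene Col5a2 rose 8.27-fold (3.05, SE 0.55, adjusted p = 0.0337, and 5-fold without day 6 replicate 3), and Pcolce, which makes an enhancer of procollagen processing, rose 6.1-fold (2.61, SE 0.51, adjusted p = 0.0443). Cthrc1, a secreted protein gene of matrix-forming cells, rose 4.4-fold (2.14, SE 0.34, adjusted p = 0.0216). Cdkn1a, which halts the cell cycle, rose 3.34-fold (1.74, SE 0.23, adjusted p = 0.00364), B2m 2.34-fold (1.23, SE 0.19, adjusted p = 0.0111), the signalling adaptor gene Pik3ap1 4.83-fold (2.27, SE 0.36, adjusted p = 0.0216) and Glipr1 3.61-fold (1.85, SE 0.35, adjusted p = 0.0367).

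In the list tests, extracellular matrix genes passed with 1 of 48 risen and 17 adjusted over the list alone (median 1.04, adjusted p = 1.0e-21, but 0.0614 with an estimated correlation). Macrophage and osteoclast genes passed with 0 of 23 called and 6 risen adjusted over the list alone (median 0.96, adjusted p = 2.0e-07, but 0.298 with an estimated correlation). Cd52 had a difference of at least 3.14 (adjusted p = 0.0818). Interferon response genes had 1 of 17 risen, B2m, and 4 adjusted over the list alone (median 0.88, adjusted p = 7.5e-08, but 0.0642 with an estimated correlation). Osteoblast genes passed upwards with 0 of 16 called and 4 risen adjusted over the list alone (median 0.48, adjusted p = 0.00241, but 0.298 with an estimated correlation). The difference for Col1a2 was 3.20 (SE 0.66, adjusted p = 0.0562, but 0.037 after quantile normalisation and 0.0336 with the offset). Vitamin D response genes had 1 of 9 risen, Cdkn1a, the same adjusted over the list alone (median 0.38, adjusted p = 0.00306, but 0.0642 with an estimated correlation). Sparc alone, at 1.20 and not called, gave adjusted p = 0.0405 for the RT-PCR markers, but 0.202 in the run with estimated correlations, which a list of 1 gene does not have.

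Pluripotency genes passed downwards with 0 of 28 called and 5 fallen adjusted over the list alone (median -0.88, adjusted p = 4.8e-05, but 0.33 with an estimated correlation). Lin28a, among them, was at -2.04 (adjusted p = 0.135). Cell division genes passed downwards with 0 of 37 in either count (median -0.37, adjusted p = 7.7e-07, but 0.311 with an estimated correlation). Cardiac genes passed upwards with 0 of 22 in either count (median 0.86, adjusted p = 7.5e-05, but 0.314 with an estimated correlation and 0.724 without day 6 replicate 3). Smooth muscle (13 measured, median 0.67, adjusted p = 0.0307, but 0.373 with an estimated correlation), endoderm (27, median 0.39, adjusted p = 0.0315, but 0.674), adipocyte (7, median 0.27, adjusted p = 0.0427, but 0.298) and, downwards, primitive streak genes (23, median -0.46, adjusted p = 0.0487, but 0.615) passed with 0 called, and with 1, 1, 2 and 0 members adjusted over the list alone. Primitive streak genes did not pass after quantile normalisation (adjusted p = 0.0544). These 4 lists did not pass without day 6 replicate 3 (adjusted p = 0.169, 0.482, 0.163 and 0.355). Nor did smooth muscle without day 8 replicate 1 (0.0892) or endoderm without day 8 replicate 2 (0.412). Adipocyte genes were lost without day 6 replicate 1, day 8 replicate 1 or day 8 replicate 2 (0.0549, 0.0799 and 0.124), and streak genes without day 6 replicate 2 or day 8 replicate 3 (0.0572 and 0.187). Sparc's list was lost without day 6 replicate 1, day 6 replicate 3, day 8 replicate 2 or day 8 replicate 3 (adjusted p = 0.072, 0.101, 0.0703 and 0.06).

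Within 1 scan batch on both chips, 22 probe sets passed, all higher, and 2272 had an unadjusted p under 0.05. With the replicate number as a block 78 passed, 75 higher and 3 lower, and Col1a2 (adjusted p = 7.8e-04) and Cd52 (0.0405) were then called as higher and Hoxb1 (0.0377) and the pluripotency list member Dnmt3b (-1.68, 0.0443) as lower. The count was 1 without day 6 replicate 3, 1 without day 8 replicate 1, 8 without day 8 replicate 2 and 37 without day 8 replicate 3. Without day 8 replicate 1, Col5a2 (adjusted p = 0.364), Pcolce (0.457), Cthrc1 (0.213), Cdkn1a (0.0674), B2m (0.202), Pik3ap1 (0.213) and Glipr1 (0.42) were not called. All but Cdkn1a were also lost without day 6 replicate 3 (0.123 to 0.311), all but Cdkn1a and B2m without day 8 replicate 2 (0.0568 to 0.108), and Pcolce and Glipr1 without day 6 replicate 2 (0.0964 and 0.102).

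From day 8 to day 16 Cyp24a1 rose 18.2-fold, from 9.01 ± 0.20 to 13.19 ± 0.10 (SD, n = 3; 4.18, SE 0.54, adjusted p = 9.8e-05), and so did its other probe set. Cyp26b1, an enzyme gene that clears retinoic acid, rose 10.4-fold (3.38, SE 0.54, adjusted p = 0.00259). The keratin gene Krt7, of simple epithelium, rose 7.15-fold (2.84, SE 0.31, adjusted p = 2.4e-05), and Krt15, of basal stratified epithelium, at least 43.3-fold (adjusted p = 2.4e-05, 23.5-fold and 88.3-fold without day 16 replicates 1 and 3). Fndc3c1 was 7.23-fold lower (-2.85, SE 0.35, adjusted p = 3.0e-04) and the integrator subunit gene Ints6 5.46-fold lower (-2.45, SE 0.44, adjusted p = 0.00244), without a change past the threshold in the 3 other probe sets of Ints6.

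The acute phase gene Saa3 rose (12.1-fold, adjusted p = 0.0104, lost without day 16 replicate 1, day 16 replicate 2 or day 8 replicate 3 at 0.0543 to 0.0923). Its fold was 7.9 and 21 without day 16 replicates 1 and 3, and 20.9 and 6.48 without day 8 replicates 1 and 3. Emp1 rose too (12.1-fold, adjusted p = 0.0148, lost without day 16 replicate 2, day 8 replicate 2 or day 8 replicate 3 at 0.0507 to 0.0879), as did Krt6a (11.7-fold, 7.6-fold and 22.9-fold without day 16 replicates 1 and 3, lost without day 16 replicate 1 or 2 at 0.0747 and 0.0543). Falls whose call was lost without a single array were those of Phlda2 (at least 6.41-fold, and 10.1-fold without day 16 replicate 3, adjusted p = 0.0305, but 0.2 without day 16 replicate 1, 0.119 without day 16 replicate 2, 0.093 without day 8 replicate 2 and 0.176 without day 8 replicate 3) and Rprm (-2.14, adjusted p = 0.0204, but 0.1 without day 16 replicate 1, 0.0549 without day 16 replicate 3, 0.0812 without day 8 replicate 1 and 0.131 without day 8 replicate 3). Vax1 fell too (at least 4.02-fold, and 6.08-fold without day 16 replicate 3, adjusted p = 0.0489, but 0.0535 with the offset and 0.1 to 0.295 without any array except day 16 replicate 3).

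Among lists, simple epithelium (17 measured, 10 risen, 0 fallen, 13 and 0 adjusted over the list alone, median 1.55, adjusted p = 2.8e-15, and 0.00308 with an estimated correlation) passed with both correlations. So did stratified epithelium (14 measured, 6 risen, 0 fallen, 8 and 0 adjusted over the list alone, median 1.57, adjusted p = 1.4e-07, and 0.0229 with an estimated correlation). Lcn2 rose at least 21.1-fold (adjusted p = 0.00526, 34.8-fold without day 16 replicate 3) and Krt14 at least 27.7-fold (16.3-fold and 49-fold without day 16 replicates 1 and 3). Vitamin D response genes had 2 of 9 risen and 0 fallen, Cyp24a1 and Cdkn1a (1.15, adjusted p = 0.00551), with 3 and 0 adjusted over the list alone (median 1.31, adjusted p = 3.8e-04, and 0.0207 with an estimated correlation). Stress and hypoxia genes had 6 of 26 risen and 0 fallen, 13 and 0 adjusted over the list alone (median 0.78, adjusted p = 1.6e-10, and 0.00308 with an estimated correlation). Among them were the hypoxia targets Ndrg1 (4.98-fold, adjusted p = 8.3e-05), Car9 (4.78-fold) and Egln3 (4.6-fold, adjusted p = 5.3e-05). Cell division genes had 6 of 37 fallen and 0 risen, 25 and 0 adjusted over the list alone (median -0.71, adjusted p = 2.1e-18, and 0.0454 with an estimated correlation). They included Plk1 (-1.02, adjusted p = 0.0174, but 0.131 without day 16 replicate 1, 0.0877 without day 8 replicate 2 and 0.0809 without day 8 replicate 3).

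Extracellular matrix genes had 13 of 48 risen and 1 fallen, 23 and 1 adjusted over the list alone (median 1.02, adjusted p = 1.6e-13, but 0.0536 with an estimated correlation). Bgn, a proteoglycan gene of bone, was 9.52-fold higher (3.25, SE 0.53, adjusted p = 0.00101). Erythroid genes had 1 of 13 fallen and 0 risen, 7 and 0 adjusted over the list alone (median -2.08, adjusted p = 8.3e-07, but 0.0654 with an estimated correlation). Alas2, the haem synthesis gene of red cells, was at least 10.6-fold lower (adjusted p = 0.0163, but 0.0793 without day 16 replicate 1 and 0.136 and 5.66-fold without day 8 replicate 3). Cardiac genes had 0 of 22 called and 1 fallen adjusted over the list alone (median -1.51, adjusted p = 8.5e-06, but 0.237 with an estimated correlation). The difference for Myl7 was -2.51 (adjusted p = 0.0563, but 0.0408 with the offset and 0.0222 with the replicate number as a block). Endothelial genes had 2 of 16 fallen and 0 risen, 3 and 0 adjusted over the list alone (median -0.81, adjusted p = 3.8e-04, but 0.237 with an estimated correlation). Tek was 4.69-fold lower (-2.23, adjusted p = 0.00951, but 0.0525 without day 16 replicate 1 and 0.0809 without day 8 replicate 3). Primitive streak genes passed downwards, with Kdr the 1 of 23 fallen in both counts (median -0.38, adjusted p = 0.0216, but 0.409 with an estimated correlation, 0.0626 without day 16 replicate 3 and 0.0581 without day 8 replicate 2). Kdr itself (-1.89, adjusted p = 0.0271) lost its call without any 1 of the 6 arrays (0.061 to 0.128). Macrophage genes passed upwards with 0 of 23 in either count (median 0.68, adjusted p = 2.7e-04, but 0.376 with an estimated correlation). Osteoblast genes had 0 of 16 in either count and did not pass (adjusted p = 0.515).

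This step lies within 1 scan batch on both chips and called 589 probe sets (1.69% of those tested), 456 higher and 133 lower. The count was 236 without day 16 replicate 1, 292 without day 8 replicate 3, 315 without day 16 replicate 2 and 384 without day 8 replicate 2.

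Over the longer span from day 6 to day 16, inside the same scan batch and added after the data were examined, the proteoglycan gene Dcn rose 67.8-fold, from 9.24 ± 0.89 to 15.32 ± 0.56 (SD, n = 3; 6.08, SE 0.70, adjusted p = 1.2e-05), and Igfbp7 and the collagen cross-linking enzyme gene Lox rose 32.5-fold and 32.4-fold. Mgp, which keeps mineral out of soft tissue, rose at least 17.3-fold (adjusted p = 0.00469, 9.7-fold and 34.5-fold without day 16 replicates 1 and 3). Saa3 (49.9-fold, or 32.6-fold and 86.6-fold without day 16 replicates 1 and 3) and Emp1 (36.7-fold) rose as well. The embryonic globin gene Hbb-bh1 was 35.5-fold lower (-5.15, SE 1.24, adjusted p = 0.00943, and -5.82 without day 6 replicate 3), Phlda2 at least 16.6-fold lower (26.2-fold without day 16 replicate 3), Fndc3c1 9.22-fold (-3.20), Snhg14 7.43-fold (-2.89) and the apelin receptor gene Aplnr 10.4-fold lower (-3.38, adjusted p = 0.0479, but 0.0625 to 0.14 without any 1 of the 6 arrays).

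Extracellular matrix genes had 34 of 48 risen and 1 fallen, 39 and 1 adjusted over the list alone (median 1.83, adjusted p = 1.8e-25, and 0.0167 with an estimated correlation). Cell division genes had 28 of 37 fallen and 0 risen, 32 and 0 adjusted over the list alone (median -1.07, adjusted p = 1.4e-20, and 0.0336 with an estimated correlation). The helicase gene Mcm5 was 3.61-fold lower (-1.85, adjusted p = 7.8e-04). Vitamin D response genes had 4 of 9 risen and 0 fallen, 5 and 0 adjusted over the list alone (median 1.92, adjusted p = 2.8e-05, and 0.0167 with an estimated correlation). Cyp24a1 was 22.5-fold and Cdkn1a 7.43-fold higher. Simple epithelium (9 of 17 risen, 0 fallen, 10 and 0 adjusted over the list alone, adjusted p = 1.1e-07, and 0.0275 with an estimated correlation) also passed with both correlations. So did stress and hypoxia genes (11 of 26 risen, 1 fallen, 15 and 2 adjusted over the list alone, adjusted p = 4.8e-06, and 0.0252 with an estimated correlation). Krt7 rose 10.6-fold and Car9 6.45-fold. Macrophage and osteoclast genes had 11 of 23 risen and 0 fallen, 15 and 0 adjusted over the list alone (median 1.85, adjusted p = 3.9e-09, but 0.123 with an estimated correlation). The protease gene Ctss was at least 21.7-fold higher (adjusted p = 0.00427, 42.3-fold without day 16 replicate 3). Osteoblast genes had 5 of 16 risen and 0 fallen, 5 and 1 adjusted over the list alone (median 0.41, adjusted p = 0.0169, but 0.308 with an estimated correlation and 0.0578 without day 6 replicate 3). They included Col1a2 (13.5-fold, adjusted p = 7.8e-04, and 8.31-fold without day 6 replicate 3), Serpinf1 (5.14-fold) and Sparc (3.94-fold, adjusted p = 0.003), whose own list of 1 gene gave adjusted p = 0.0406, but 0.123 in the run with estimated correlations and 0.056, 0.0578 and 0.0724 without day 6 replicate 1, day 6 replicate 3 and day 16 replicate 3.

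Stratified epithelium genes rose with 6 of 14 and 0 fallen, 7 and 0 adjusted over the list alone (adjusted p = 2.5e-05, but 0.0568 with an estimated correlation). Krt15 rose at least 43.3-fold (23.5-fold and 88.3-fold without day 16 replicates 1 and 3). Interferon response genes had 4 of 17 risen and 0 fallen, 6 and 0 adjusted over the list alone (adjusted p = 0.00155, but 0.194 with an estimated correlation). H2-D1 was 6.94-fold higher. Adipocyte genes had 2 of 7 risen, Cebpb (9.33-fold) and Lpl (9.27-fold), with 3 and 1 adjusted over the list alone (adjusted p = 0.0201, but 0.136 with an estimated correlation and 0.0555 without day 6 replicate 3). Endoderm genes had 5 of 27 risen and 0 fallen, the same adjusted over the list alone (adjusted p = 0.0047, but 0.461 with an estimated correlation, 0.108 without day 16 replicate 3 and 0.0578 without day 6 replicate 3). Ambp was at least 4.36-fold higher (7.11-fold and 2.86-fold without day 16 replicates 1 and 3). Downwards, erythroid genes had 5 of 13 fallen and 9 adjusted over the list alone (median -2.41, adjusted p = 2.0e-05, but 0.122 with an estimated correlation). Pluripotency genes had 5 of 28 fallen, such as Lin28a at -2.61, and Klf4, also a gene of differentiating epithelium, risen 6-fold, with 6 and 1 adjusted over the list alone (adjusted p = 0.0029, but 0.407 with an estimated correlation). Primitive streak genes had 5 of 23 fallen, the same adjusted over the list alone (adjusted p = 0.00234, but 0.255 with an estimated correlation). Nkx1-2 was 3.88-fold lower (-1.96). Endothelial genes had 3 of 16 fallen and 1 risen, 4 and 1 adjusted over the list alone (adjusted p = 0.0086, but 0.308 with an estimated correlation, 0.071 without day 6 replicate 1 and 0.05 without day 6 replicate 2). Tek was 4.19-fold lower (-2.07). Hox genes had 4 of 23 fallen and 7 adjusted over the list alone (adjusted p = 0.0246, but 0.204 with an estimated correlation). Hoxb5 was at least 6.19-fold lower (adjusted p = 0.0148, but 0.0763 and 0.0648 without day 16 replicate 1 and 2 and 0.0517 without day 6 replicate 3).

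From day 6 to day 16, limma called 2201 probe sets (6.29% of those tested), 1345 higher and 856 lower. The count was 1056 without day 16 replicate 1, 1258 without day 6 replicate 3, 1391 without day 16 replicate 2 and 1429 without day 6 replicate 2.

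**Figure D4:**
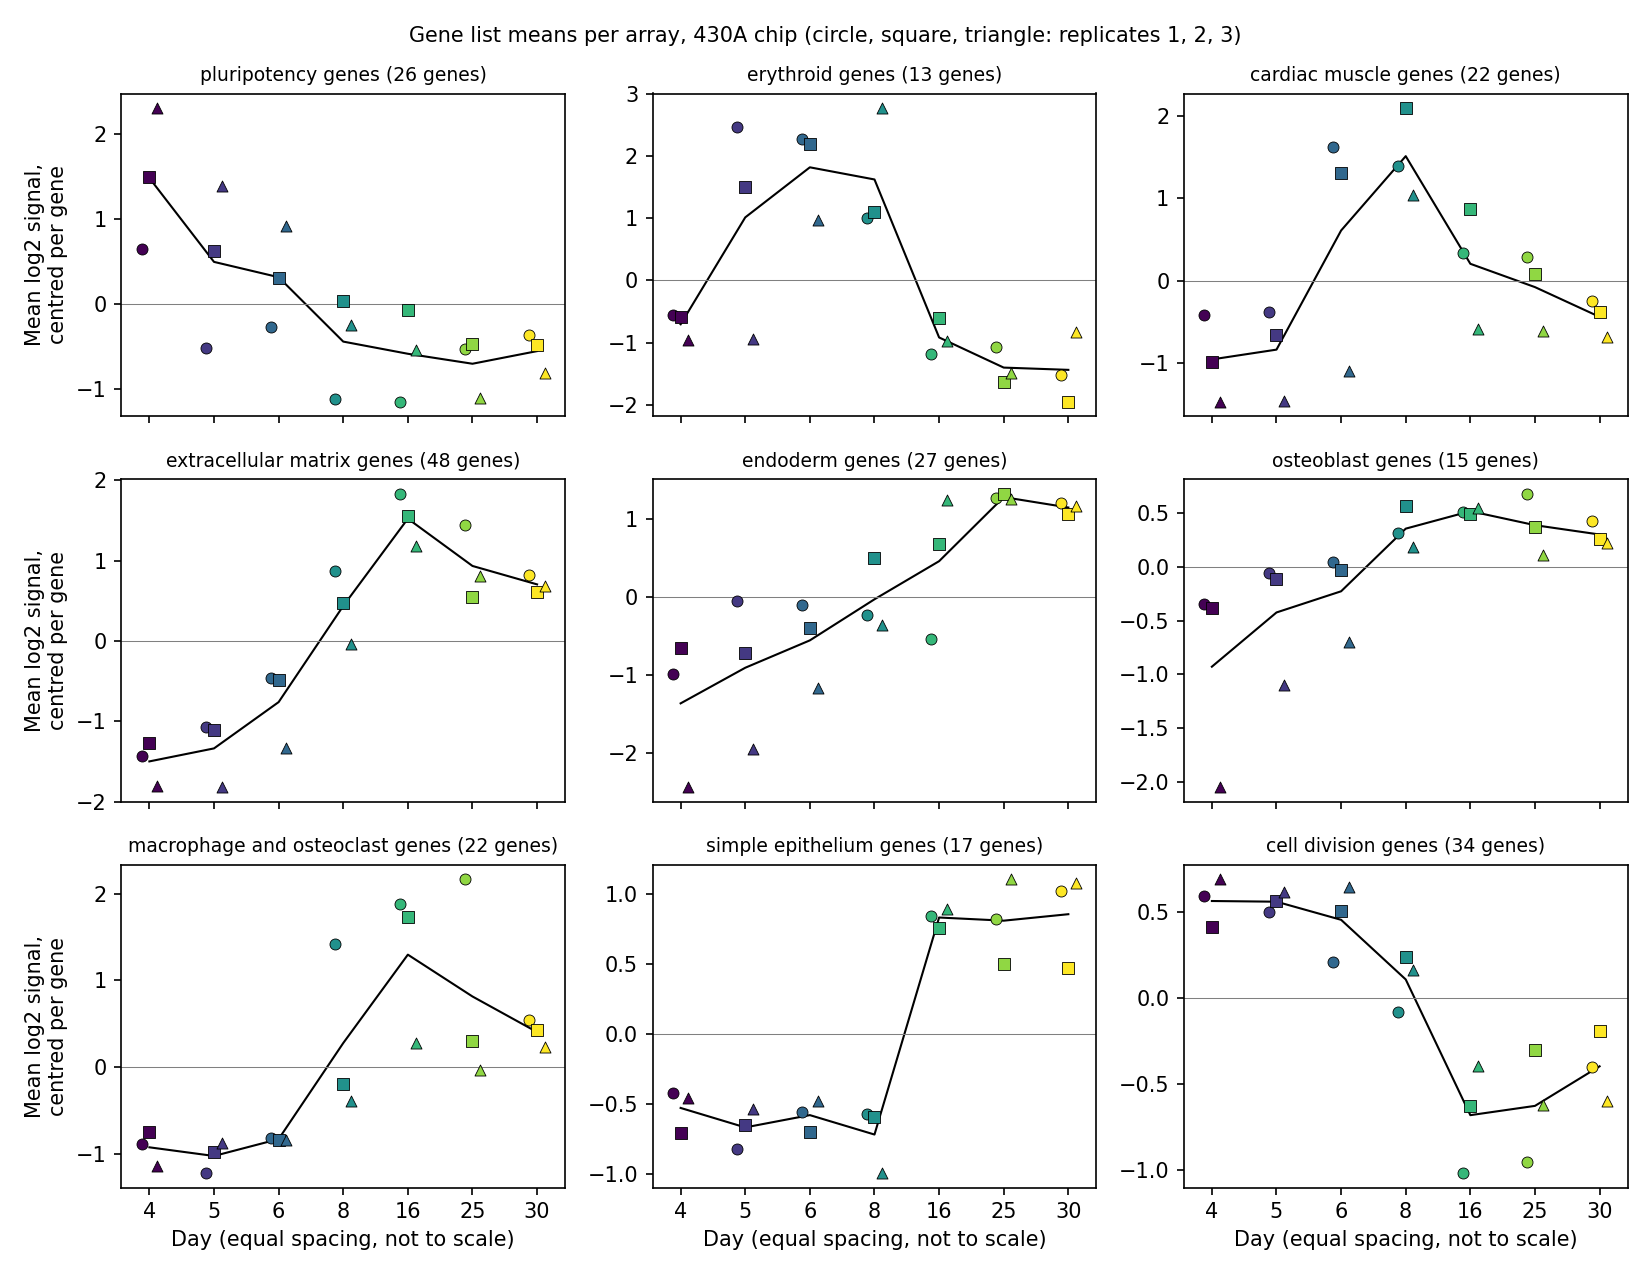
Mean centred log2 signal of 9 gene lists on the 430A chip by day, with 1 point per array. Pluripotency genes go from a mean of 1.49 on day 4 to -0.557 on day 30, and erythroid genes are highest on day 6 with a mean of 1.82.

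Between day 16 and day 25 the gastric gene Gkn2 rose 19.5-fold, from 9.35 ± 0.93 to 13.63 ± 0.63 (SD, n = 3; 4.28, SE 0.66, adjusted p = 0.00298). The water channel gene Aqp8 rose 8.36-fold (3.06, adjusted p = 0.00225, and 13.8-fold without day 16 replicate 3), the granule proteoglycan gene Srgn 6.67-fold (2.74, adjusted p = 0.00345), the protease gene Ctse 3.12-fold (1.64, adjusted p = 0.00298), and the cornified envelope gene Sprr1a 3.34-fold (1.74, adjusted p = 0.0194, but 0.071, 0.0658 and 0.0752 without day 16 replicate 2, day 16 replicate 3 and day 25 replicate 3). Mtm1 was at least 7.95-fold lower (adjusted p = 0.00225), and its other probe set fell as well. The cadherin gene Pcdh18 (-2.48, adjusted p = 0.024), the smooth muscle gene Tagln (-2.42, adjusted p = 0.0202), the imprinted gene Mest (-2.25, adjusted p = 0.0387) and Igdcc4 (-2.14, adjusted p = 0.0192) fell. Without day 25 replicate 1 Pcdh18 was at -3.27 and Mest at -2.84. Without day 25 replicate 2 these 4 were not called (0.144, 0.132, 0.222 and 0.121), nor without day 16 replicate 1 (0.104, 0.108, 0.126 and 0.093) or day 16 replicate 2 (0.112, 0.0565, 0.135 and 0.0743). Pcdh18, Tagln and Mest were also lost without day 25 replicate 3 (0.0947, 0.0583 and 0.106), and Tagln and Mest without day 16 replicate 3 (0.0518 and 0.0752).

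Osteoblast genes had 0 of 16 called and 0 and 1 adjusted over the list alone (adjusted p = 0.637), and the difference for Sparc was 0.97 (adjusted p = 0.285). Cdh11, at -2.49 (adjusted p = 0.0627), was called after quantile normalisation (0.044), with the offset (0.028) and with the replicate number as a block (0.0119). Endoderm genes passed upwards with 0 of 27 called and 5 risen adjusted over the list alone (median 0.81, adjusted p = 0.00197, but 0.837 with an estimated correlation and 0.209 without day 16 replicate 1). Lama1 was at 2.96 (adjusted p = 0.0686, but 0.0234 with the offset) and Gata4 at 1.51 (adjusted p = 0.0744, but 0.044 after quantile normalisation, 0.0454 with the offset and 0.0406 with the replicate number as a block). BMP and Wnt signalling genes passed downwards with 0 of 40 called and 6 fallen adjusted over the list alone (median -0.59, adjusted p = 0.0101, but 0.697 with an estimated correlation and 0.113 without day 25 replicate 2). Fzd2, among them, was at -1.23 (adjusted p = 0.0883). Smooth muscle genes passed downwards with Tagln the 1 of 13 fallen and 2 adjusted over the list alone (median -0.68, adjusted p = 0.0191, but 0.697 with an estimated correlation and 0.0665, 0.113 and 0.119 without day 16 replicate 1, day 25 replicate 2 and day 25 replicate 3). Extracellular matrix genes passed downwards although the 2 of 48 called had risen, Lamb1 (1.63, adjusted p = 0.0478) and Plod2 (1.30, adjusted p = 0.0461), with 6 risen and 7 fallen adjusted over the list alone (median -0.76, adjusted p = 0.0209, but 0.897 with an estimated correlation and 0.227, 0.228 and 0.0611 without day 16 replicate 1, day 25 replicate 2 and day 25 replicate 3). Lamb1 and Plod2 were lost without day 25 replicate 2 (adjusted p = 0.256 and 0.228), day 25 replicate 3 (0.127 and 0.107), day 16 replicate 1 (0.25 and 0.207) or day 16 replicate 2 (0.136 and 0.11), and Plod2 without day 16 replicate 3 (0.0725). Stress and hypoxia genes passed upwards with 0 of 26 called and 1 risen adjusted over the list alone (median 0.30, adjusted p = 0.0253, but 0.697 with an estimated correlation and 0.06, 0.186, 0.0528 and 0.289 without day 16 replicate 1, day 16 replicate 3, day 25 replicate 2 and day 25 replicate 3). After quantile normalisation the list did not pass (0.231). The difference for Pgk1 was 0.88 (adjusted p = 0.0547, but 0.0333 with the offset).

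The step called 121 probe sets (0.346% of those tested), 51 higher and 70 lower, or 31 and 71 after median centring, and it lies wholly between scan batches, so day and batch cannot be told apart. The Gapdh 3'/5' ratio rose from 2.55 to 3.84, and with it as a covariate 1 probe set passed. On 430A its values did not overlap between the days (2.37 to 2.65 on day 16 and 3.42 to 4.13 on day 25). The covariate and day therefore change together, and this fit cannot tell RNA shortening from other differences between the days. The count was 316 without day 25 replicate 1, 26 without day 25 replicate 2, 63 without day 25 replicate 3, 22 without day 16 replicate 1, 22 without day 16 replicate 2 and 68 without day 16 replicate 3.

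From day 25 to day 30, the last step of the course, no gene was called. Sparc was at 16.41 ± 0.57 on day 25 and 17.03 ± 0.23 on day 30 (SD, n = 3; 0.61, SE 0.41, adjusted p = 0.999). The stem cell gene Pou5f1, lower on day 30 than on day 4, had a difference of at least 0.75 (adjusted p = 0.825). Cell division genes passed upwards with 0 of 37 in either count (median 0.23, adjusted p = 3.5e-04, but 0.701 with an estimated correlation, 0.733 without day 25 replicate 1 and 0.0732 without day 30 replicate 2). Smooth muscle genes passed downwards with 0 of 13 in either count (median -0.51, adjusted p = 0.00996, but 0.701 with an estimated correlation, 0.733 without day 25 replicate 1, 0.0732 without day 30 replicate 2 and 0.0527 with the mean over a gene's probe sets). Among them were Synpo2 (adjusted p = 0.797) and Cnn1 at -1.32 (adjusted p = 0.996). Neural genes passed downwards with 0 of 22 in either count (median -0.50, adjusted p = 0.0457, but 0.701 with an estimated correlation and 0.733, 0.098 and 0.0749 without day 25 replicate 1, day 30 replicate 2 and day 30 replicate 3). The neural call was also lost after quantile normalisation (0.11) and with the mean over a gene's probe sets (0.0632). The difference was -0.92 for Nnat (adjusted p = 0.803), and Gap43 had an adjusted p of 0.963.

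limma called 0 probe sets in this step, while 1906 had an unadjusted p under 0.05, 853 on 430A and 1053 on 430B. On simulated data, 53.0% of 4-fold changes were called, which need not hold for these days. The count was 12 without day 30 replicate 1, 10 without day 30 replicate 3, 9 without day 25 replicate 3, and 4 without day 25 replicate 1 or without day 30 replicate 2.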

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

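The culture number as a block, the Gapdh ratio as a covariate, scan batch as a random block, the replicate block on the compared days alone, the fits without day 4 replicate 2 and day 25 replicate 1, leaving out each array for the named genes, every alternative for the osteoblast marker courses, and every result for day 16 with day 6 were chosen after the data were examined. No called result for a named gene changed direction under quantile normalisation, the offset, the replicate block or the fit with the highest p when each array was left out, and no called list did under the alternatives for lists. Of 464 results for named genes, 231 past the threshold, 453 kept their side of it under quantile normalisation (7 lost and 4 gained the call), 446 with the offset (5 lost and 13 gained it), 447 with the replicate block (1 lost and 16 gained it) and 378 when each array was left out in turn (86 lost it in at least 1 fit, and gains were not counted). Of 192 list results, 69 past the threshold, 188 kept their side under quantile normalisation (3 lost and 1 gained the call), 188 with the mean over a gene's probe sets (2 lost and 2 gained it), 167 when each array was left out, and 134 with an estimated correlation, where 58 lost the call. Lists past the test went from 14 to 1 for day 30 with day 4, from 2 to 0 for day 5 with day 4, 4 to 0 for day 6 with day 5, 13 to 0 for day 8 with day 6, 11 to 5 for day 16 with day 8, 5 to 0 for day 25 with day 16, 3 to 0 for day 30 with day 25 and 17 to 5 for day 16 with day 6. That run also uses fewer degrees of freedom, and what ended the calls was not tested. Of the 58, 3 were the list with Sparc alone, which has no correlation to estimate. With the mean over a gene's probe sets, 1 list passed for day 30 with day 25.

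Counts of changed probe sets moved by over 1.5 times as follows, and the cause was not tested. For day 30 with day 4, 3929 passed with only the arrays of those days. For day 5 with day 4 (2 called), it was 1 with the offset, 1 with the filter at the 60th percentile, 7 with the replicate block, 9 with the culture block and 0 with only those days (limma, against 2598 at an unadjusted p under 0.05 with all days). For day 6 with day 5 (19 called), it was 10 with quantile normalisation, 8 with no filter, 7 without the trend, 42 with the replicate block, 35 with the culture block, 10 with the Gapdh covariate, 29 with scan batch as a random block and 0 with only those days (2431 unadjusted with all days). For day 8 with day 6 (22 called), it was 65 with the offset, 9 without the trend, 78 with the replicate block, 72 with the culture block, 14 with the Gapdh covariate, 8 with only those days and 108 with only those days and the replicate block. For day 16 with day 8, it was 967 with only those days. For day 25 with day 16 (121 called), it was 229 with the offset, 234 with the replicate block, 1 with the Gapdh covariate and 12 with only those days. For day 30 with day 25 (0 called by limma, 1906 unadjusted), it was 1 with the Gapdh covariate and 38 with scan batch as a block. The batch block could not be estimated for day 30 with day 4, day 25 with day 16 and, on 430A, day 6 with day 5.

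Leaving out each array in turn gave 6984 to 8050 for the F test, 4947 to 5746 for day 30 with day 4, 1 to 209 for day 5 with day 4, 2 to 91 for day 6 with day 5, 1 to 37 for day 8 with day 6, 236 to 516 for day 16 with day 8, 22 to 316 for day 25 with day 16, 0 to 12 for day 30 with day 25 and 1056 to 1834 for day 16 with day 6. Without both day 4 replicate 2 and day 25 replicate 1, these were 4 for day 5 with day 4, 33 for day 6 with day 5, 40 for day 8 with day 6, 810 for day 16 with day 8, 530 for day 25 with day 16, 5 for day 30 with day 25 and 2870 for day 16 with day 6. Lists past the test ranged from 12 to 14, 1 to 9, 4 to 8, 8 to 12, 11 to 13, 1 to 7, 0 to 6 and 14 to 17, in the order of the 8 comparisons above. The lowest were 1 for day 5 with day 4 without day 4 replicate 3 or day 5 replicate 1, 8 for day 8 with day 6 without day 6 replicate 3, 1 for day 25 with day 16 without day 25 replicate 2, and 0 for day 30 with day 25 without day 25 replicate 1 or day 30 replicate 2. The osteoblast marker calls, 30 in all, ranged from 27 to 36. Over the 7 days 9.71% of tested probe sets were called on 430B against 36.2% on 430A, and whether signal near background limits the calls on 430B was not tested.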

Other observations

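The tests on replicate 3 of days 4 to 6, and the counts for day 16 with day 6, were chosen only after the result was seen. List means differed between replicates of a day. The mean of the macrophage and osteoclast genes, in centred log2 signal, was -0.83 ± 0.01 on day 6 (SD, n = 3), then 1.42, -0.20 and -0.39 in the 3 replicates of day 8, 1.88, 1.73 and 0.28 on day 16, and 2.17, 0.31 and -0.03 on day 25. On day 30 the 3 arrays lay closer, at 0.55, 0.43 and 0.23. Skeletal muscle genes, which passed no list test with all arrays and at most 2 of the 6 fits of a comparison without 1 array, were at 1.49, 0.58 and -0.64 on day 16, 1.79, 1.24 and -0.48 on day 25 and 0.77, 0.57 and -0.44 on day 30, lowest in replicate 3 each time. The settings files write replicate 3 as culture 4 on day 16 and as culture 3 on days 25 and 30.

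Erythroid genes were at 2.47, 1.5 and -0.93 on day 5, 2.27, 2.20 and 0.98 on day 6, and 1.00, 1.10 and 2.77 on day 8. So replicate 3 was lowest on days 5 and 6, where the settings files write it as culture 3, and highest on day 8, where they write culture 4. Cardiac genes were at 1.62, 1.30 and -1.09 on day 6 and 1.39, 2.09 and 1.04 on day 8. Pluripotency genes were highest in replicate 3 on day 4 (0.65, 1.49 and 2.31), day 5 (-0.53, 0.62 and 1.39) and day 6 (-0.28, 0.30 and 0.92).

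The rise of Sparc to day 30 may come in part from cells with endoderm genes, which also make basement membrane. Within days, the correlation of Sparc with the endoderm genes was r = 0.68 (95% interval 0.27 to 0.89, permutation p = 0.0273, but 0.314 adjusted over 23 lists, and r = 0.44 without the 2 farthest samples). The permutation and the interval treat the days as independent, although Sparc was lowest in replicate 3 on days 4, 5 and 6. The endoderm mean hardly varied within day 25 (SD 0.038) or day 30 (0.073), against 0.945, 0.961 and 0.91 on days 4, 5 and 16. The correlation thus bears little on the rise of Sparc after day 16. With the osteoblast genes r was of the same size but did not pass (r = 0.68, 0.25 to 0.88, permutation p = 0.0587, 0.353 adjusted, r = 0.38 without the 2 farthest). So for the osteoblast genes as the source the test stays open, and the sources cannot be told apart. The correlation with Sparc was negative for pluripotency genes (r = -0.61, permutation p = 0.0613, 0.353 adjusted) and interferon response genes (r = -0.58, permutation p = 0.0202, 0.314 adjusted). Neither passed when adjusted over the 23 lists. The lowest deviations of Sparc, -1.14 and -0.89, were those of replicate 3 on days 5 and 4, where pluripotency genes were highest. A difference in stage between replicates was not tested for Sparc and stays open. No measurement of single cells is among the samples.

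For the genes higher on day 6 than on day 5, a difference between scan batches stays open. Day 5 replicate 1 was scanned with day 6 on 430B and with day 4 on 430A, and lay between the days at 0.546 and 0.556 (difference -0.01). Replicates 2 and 3 lay at 0.464 and 0.563 (-0.099) and at 0.529 and 0.586 (-0.057) on these chips. In size the difference lies within those, which was the bound set against a batch difference, but with its sign it lies above them, and a single array links the batches on 430B only. Day and batch cannot be told apart here.

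Replicate 3 of days 5 and 6 may be behind the others in the course: its deviation from replicates 1 and 2 ran against the later change on both days (r = -0.16 and -0.331). The test was first made over days 4 to 6 and split after its result was seen, as day 4 replicate 3 gave 0.00. Replicates 1 and 2 gave 0.101 and 0.029 there, so a lag on day 4 stays open. RNA quality of replicate 3 is argued against by its control ratios, which lay at the same end of the 3 replicates on at most 1 of 3 days. A swap of RNAs between days within replicate 3 stays open, since its positions along the course rose from 0.184 to 0.242 and 0.428, with a smallest step of 0.06 against a pooled SD of 0.14 in replicates 1 and 2, a bound chosen after the value was seen. No other biological explanation was tested.

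Other splits of the samples were counted for each comparison. Chance is excluded for the F test over the 7 days, as 1 of 100 regroupings, the real one with 7822, gave as many, and the highest of the others gave 822. For 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real value and the highest other were 6082 and 4 for day 30 with day 4, 589 and 2 for day 16 with day 8, 121 and 14 for day 25 with day 16, 0 and 6 for day 30 with day 25 (10 of 10 as large), and 2201 and 1 for day 16 with day 6.

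For day 5 with day 4 the real split gave 2, and 5 of 10 splits gave as many. The highest, 439, set day 5 replicates 1 and 2 and day 4 replicate 1 against the rest, which points to a structure of the samples. For day 6 with day 5 the real split gave 19 and the highest other 77 (2 of 10 as large), for day 6 replicates 1 and 2 with day 5 replicate 1, also a structure of the samples. On 430B, where day 5 replicate 1 shares the scan batch of day 6, that split gave 14 of the 77, and with scan batch as a block on that chip the days differ in 3 probe sets against 2 without. For day 8 with day 6 the real split gave 22 and the highest other 1. Among the 4 splits that part all replicate pairs, the highest other was 2 for day 5 with day 4 and 0 for day 8 with day 6.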
